A study of Mus musculus with 25 samples.

How the data were processed

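The series holds 25 samples from C57BL/6 mice, of which 20 are analysed here. RNA was sequenced in 12 libraries of B cells enriched by magnetic depletion of CD43-positive cells. These are 2 control and 2 Pax5-deficient libraries each of lymph node cells taken ex vivo, of cells treated with anti-IgM for 1 hour, and of cells cultured with anti-CD40 and interleukin 4 for 2 days. Small RNA was sequenced in 8 libraries of B cells sorted magnetically for CD23, 2 control and 2 deficient from spleen (follicular B cells) and the same from lymph node. Per the labels small RNAs were size-selected from total RNA by the mime-seq protocol, without a statement on whether microRNAs of a certain cell type were enriched. The other 5 samples, 2 of histone H3K4me2, 2 of DNase hypersensitivity and 1 of biotin-tagged Pax5 binding, are not analysed here. The anti-CD40 libraries carry another library label than the other RNA libraries, so culture and preparation cannot be told apart where they are compared with them. The labels give no sequencing batch and no replicate numbers that groups share. The cell labels of the anti-IgM and anti-CD40 libraries name no organ.

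For RNA the deposited unit is TPM (transcripts-per-million), computed by the authors, and the 24732 listed genes of each library sum to the same total. Per the submitters' processing notes HTSeq 0.6.1p1, MACS 1.3.6.1, DESeq2 1.8.2 and the genome build mm9 were used in the series, without a stated role for each. Every value could be written as a whole number of reads divided by a gene length that was common to the libraries, to a relative deviation of 1e-09, and these reads were recovered for alternative fits. Tested on simulated data, the recovery returned whole reads for 3000 of 3000 genes and the true reads for 2996, and in each control without such structure it did so for 23 of 3000. Of the gene names 22499 matched a RefSeq symbol, 1382 a synonym and 851 neither. A suffix on 3539 names that appears to mark overlap with another gene (Pik3cd, Cd72, Irs2 and Rasd1 among those in the text) is not explained in the files, so part of their reads could come from a neighbour. For small RNA the deposited unit is expected counts per row of a microRNA arm and genomic copy, since between 26.4% and 30.1% of the counted rows per library were not whole. The total of the 2 count columns was rounded and used, and a mark column was not used. Per the submitters' processing notes DESeq2 1.18.1 and the builds mm9 and mm10 were used for small RNA. Spleen files list 1394 rows and lymph node files 1512.

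RNA depth per library, as recovered reads, was 24838490 and 21812705 for lymph node control, 29590077 and 26647023 for lymph node deficient, 22627267 and 22289021 for anti-IgM control, and 23235572 and 29973505 for anti-IgM deficient. It was 16341341 and 7686980 for anti-CD40 control, and 18532881 and 11562440 for anti-CD40 deficient. Small RNA totals were 25069685 and 16027072 for spleen control, 13649660 and 6635658 for spleen deficient, 19567059 and 16341390 for lymph node control, and 21166212 and 20245132 for lymph node deficient. Replicates correlated with r between 0.985 and 0.998 on the log2 scale, over genes with at least 10 counts. Their spread exceeded counting error, with a chi-square per degree of freedom of 5.13 to 20.9 for RNA and 33.5 to 333 for small RNA.

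RNA was tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2 of TPM plus a pseudocount of 1, for genes with at least 1 TPM in at least 2 libraries of the fit. Lymph node and anti-IgM libraries shared 1 fit of 8 libraries with 1 coefficient per group, and the anti-CD40 libraries had a fit of their own. The fits gave the genotype effect in each condition, the response to anti-IgM in each genotype, and the difference between these responses. Small RNA was tested with edgeR 4.0.16 by quasi-likelihood on all 8 libraries, with TMM scaling and filterByExpr, for the genotype effect in each organ and the difference between organs. P values were adjusted by Benjamini-Hochberg, and an adjusted p of 0.05 was the threshold. These choices, the comparisons and the rule for naming genes were made before the data were examined.

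The text names Pax5 and Pten, the 10 genes with the largest change in each direction (5 for the difference of responses, 8 for microRNAs) among those past the threshold, and up to 4 members per list. Named genes needed a mean of at least 5 TPM in a group, and named microRNAs 10 TMM-scaled CPM (counts-per-million). This minimum and the leaving out of names without a symbol were added after values had been seen. Genes called in opposite directions in lymph node and anti-CD40 cells, and the gene groups in the last part of the closing section, were chosen after their values were seen. Lists were tested with camera at its preset correlation of 0.01 and again with an estimated correlation. The 25 gene lists were B cell receptor signalling, known Pax5-activated and Pax5-repressed genes, PI3K pathway genes (activating and restraining), FOXO targets, NF-kB targets, immediate-early genes, stress and dissociation genes, activation and class switch genes, plasma cell genes, ribosome biogenesis, cell cycle, glycolysis, cholesterol synthesis and interferon response genes, and markers of follicular, germinal centre, marginal zone and B1, T, NK, myeloid, dendritic, erythroid and platelet, and stromal and endothelial cells. The 9 microRNA lists were the miR-29, let-7, miR-181 and miR-17~92 families, microRNAs known to target Pten, and microRNAs of lymphocytes, myeloid, erythroid and platelet, and endothelial and stromal cells. List members were written from general knowledge.

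Alternatives for RNA were pseudocounts of 0.1 and 5, no filter and a filter at 5 TPM, median-ratio rescaling, rescaling without immunoglobulin and T cell receptor segments, robust hyperparameters, 1 fit of all 12 libraries, fits of the compared groups alone, a threshold of 2-fold, and leaving out each library in turn. For small RNA they were RLE size factors, DESeq2 1.42.0, no filter, fits of 1 organ alone, copies of a microRNA summed, and leaving out each library. Added after seeing the data were edgeR and DESeq2 on the recovered reads, scaling to library totals, 1 of the 2 count columns alone, median-ratio rescaling of the lists, and a test of the difference between lymph node and anti-CD40 effects.

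The tests were tested on simulated data with the same group sizes. All genes and groups of a fit shared the same simulated dispersion. The real groups did not, with a chi-square per degree of freedom of 5.13 in lymph node control and 19.3 in lymph node deficient libraries. The shares below may therefore differ from those of the real comparisons. In a simulation like the lymph node comparison limma recovered 73.1% of 1.5-fold and 100% of 2-fold changes, with 9 unchanged genes called of 11817 tested. In one like the anti-CD40 comparison it recovered 4.48% of 1.5-fold, 55.2% of 2-fold and 100% of 4-fold changes, with 31 unchanged genes called. For the difference of responses the shares were 28.4% and 94.0% for 1.5-fold and 2-fold changes. For microRNAs edgeR recovered 85.1% of 2-fold changes in spleen, 82.1% in lymph node and 46.3% in the difference between organs. Camera found 10 of 10 shifted lists and 0 of 10 unshifted lists, in simulated genes that were independent of each other. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.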

Results

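Messenger RNA and small RNA were measured in mouse B cells that carried or had lost Pax5, the transcription factor that holds B cells to their lineage. The title of the series places Pax5 upstream of PI3K signalling and of Pten, the phosphatase that opposes PI3K. Control cells carried 1 floxed and 1 intact Pax5 allele with Cre under Cd23 control. Deficient cells carried 1 floxed and 1 null allele with the same Cre, which acts in mature B cells. RNA was sequenced in 12 libraries. They came from B cells taken directly from lymph nodes, from cells treated with an antibody against the IgM receptor for 1 hour, and from cells cultured for 2 days with anti-CD40 and interleukin 4. Small RNA was sequenced in 8 libraries of spleen follicular and lymph node B cells. Each genotype had 2 libraries in each condition, and nothing in the labels says that the 2 came from separate animals. The p values therefore measure spread between libraries that may be technical replicates. Means are given ± SD (n = 2).

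The RNA libraries held between 7686980 reads (anti-CD40 control, replicate 2) and 29973505 reads (anti-IgM deficient, replicate 2), as worked back from the deposited values. Between 10548 and 11813 genes reached 1 TPM in a library, and the 10 most abundant genes took between 8.70% and 13.5% of the total. The small RNA libraries held 6635658 to 25069685 counts. A single product, miR-142a-3p, took 28.4% to 50.5% of the counts in each. Each gene or microRNA called below had groups that did not overlap, which chance gives for 33.3% of genes with 2 libraries against 2.

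Pax5 transcript did not pass the limma test in any condition, though it was lower in deficient cells after anti-CD40. In lymph node cells it stood at 562 ± 58.2 TPM in deficient and 541 ± 54.5 TPM in control libraries. The log2 change of 0.06 (limma adjusted p = 0.634) turned to -0.09 after median-ratio rescaling. After anti-IgM the values were 424 ± 6.50 and 430.3 ± 10.1 TPM (log2 change -0.02, adjusted p = 0.864). After anti-CD40 they were 287 ± 13.7 and 383 ± 35.5 TPM (log2 change -0.41, interval -0.68 to -0.14, unadjusted p = 0.00996, adjusted p = 0.107). Recombination of the floxed allele removes a single exon, so the level of the whole gene does not check the loss of the protein. Pten, the phosphatase that removes the product of PI3K, was 60.0 ± 9.85 TPM in deficient and 61.4 ± 5.18 TPM in control lymph node cells. The log2 change was -0.04, with a 95% interval of -0.30 to 0.22 (adjusted p = 0.806). After anti-IgM it was 90.1 ± 5.25 and 97.3 ± 5.01 TPM (log2 change -0.11, interval -0.37 to 0.15, adjusted p = 0.443). After anti-CD40 it was 23.2 ± 4.68 and 23.0 ± 7.70 TPM (log2 change 0.04, interval -0.59 to 0.66, adjusted p = 0.955), and this direction turned with rescaling. The files hold no protein values. Pax5 lies on chromosome 4 from 44524748 to 44710694 and Pten on chromosome 19 from 32757577 to 32826160.

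**Figure D1:**
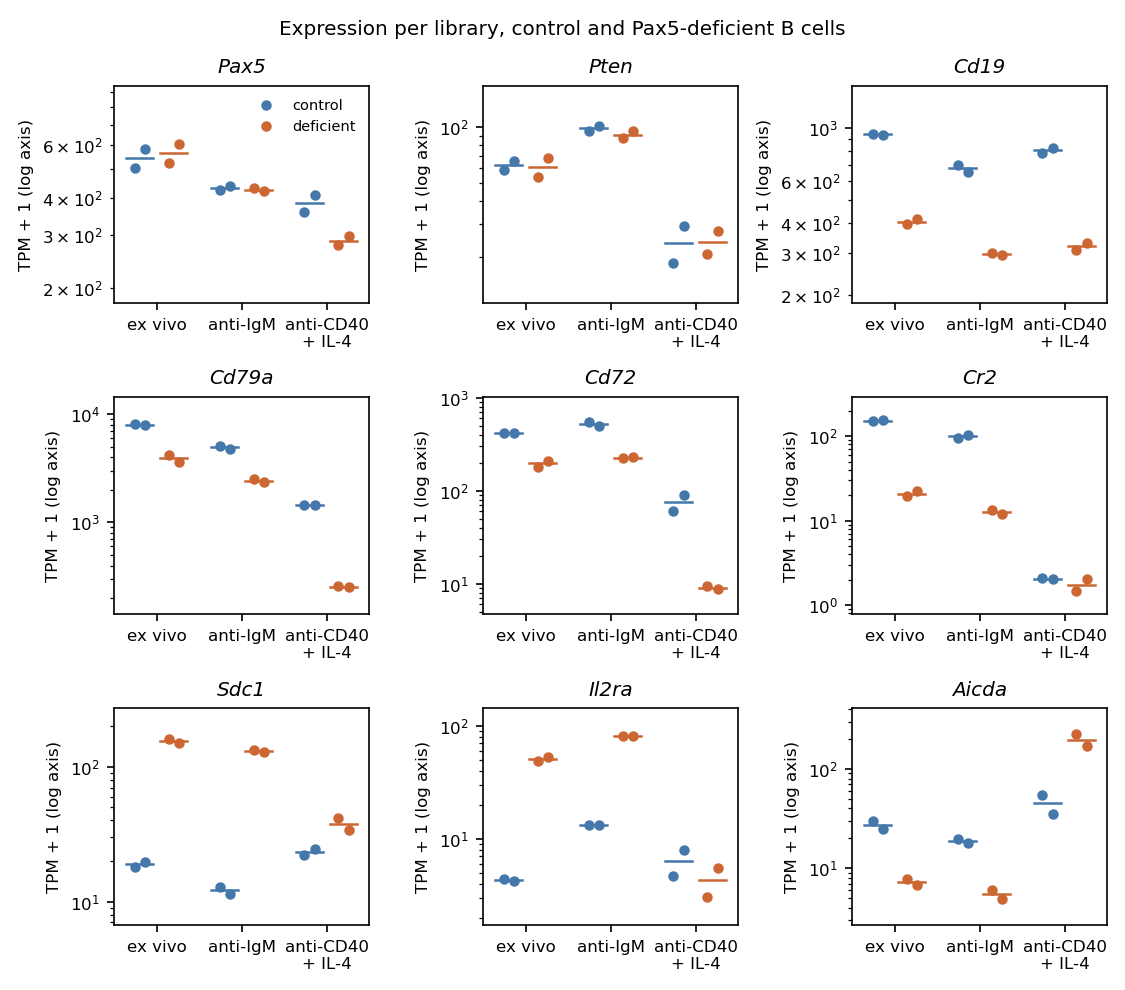
Transcript level of 9 genes in control and deficient B cells in each condition, as TPM + 1 on a log axis, with a point for each of the 2 libraries and a bar at their mean. Pten lies at like levels in both genotypes, Cd19 is lower in the deficient cells of each condition, and Sdc1 is higher in lymph node and anti-IgM libraries.

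The lymph node comparison asks what loss of Pax5 does to resting mature B cells. Il2ra, the alpha chain of the interleukin 2 receptor, rose from 3.32 ± 0.154 to 50.2 ± 2.91 TPM. Sdc1, the plasma cell surface proteoglycan syndecan-1, rose from 17.9 ± 0.974 to 154 ± 7.01 TPM. The semaphorin gene Sema6d rose by 4.53 on the log2 scale and the carbonic anhydrase gene Car2 by 3.16. The complement receptor gene Cr2 fell from 152 ± 2.22 to 19.9 ± 2.04 TPM and the complement regulator gene Cd55 from 162 ± 18.5 to 21.5 ± 5.14 TPM. The co-receptor gene Cd19, whose product recruits PI3K, fell from 938 ± 3.23 to 404 ± 15.4 TPM. Across the genome 5322 of 12084 genes tested passed the limma test, 3445 higher and 1877 lower, and 1003 of them changed at least 2-fold. Among the other genes with the largest rises were the collagen chain gene Col27a1 (log2 change 3.41), the chemokine gene Ccl3 (3.21), Cd93 (3.14), Abhd15 (2.88), the purine receptor gene P2ry13 (2.77) and the thrombomodulin gene Thbd (2.74). Among the largest falls were Stac2 (-3.15), the calcium channel gene Cacna1i (-3.04), Crisp3 (-2.79), the sodium channel gene Scn4a (-2.51), Kctd14 (-2.33), Shank1 (-2.31) and the urokinase receptor gene Plaur (-2.28). The median log2 change of all genes was 0.08 and moved to -0.05 with median-ratio rescaling, after which 2585 genes were higher and 3273 lower, so the excess of rises rests on the scale.

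Genes of the B cell receptor and its modifiers fell in lymph node cells. Of 25 genes of B cell receptor signalling, 4 rose and 14 fell (4 and 14 adjusted over the list alone). The median log2 change was -0.35 (camera adjusted p = 2.5e-05, adjusted p = 0.179 with an estimated correlation). The IgD heavy chain fell (log2 change -2.55, adjusted p = 1.98e-06), as did the adaptor gene Sh3bp2 (-1.12, adjusted p = 3.01e-05) and the inhibitory co-receptor gene Cd72 (-1.11, adjusted p = 4.19e-05). Genes known from earlier work to need Pax5 fell together. Of 24 tested, 3 rose and 17 fell (3 and 17 adjusted over the list alone). This list passed (camera adjusted p = 4.47e-08, adjusted p = 0.179 with an estimated correlation), and Bcar3 stood at 42.5 ± 0.516 against 116 ± 1.01 TPM. Of 17 genes that Pax5 is known to hold down, 12 rose and 1 fell (12 and 1 adjusted over the list alone). This list passed upward (camera adjusted p = 0.000609, adjusted p = 0.313 with an estimated correlation). The Fc receptor gamma chain gene Fcer1g stood at 115 ± 8.85 against 30.8 ± 2.75 TPM and the cytokine receptor gene Flt3 at 77.9 ± 9.89 against 26.7 ± 0.594 TPM. These genes and Csf1r are also in the lists of myeloid or dendritic cell markers, which rose in the same libraries. Follicular B cell markers fell as a list, with 2 of 13 up and 8 down (the same counts adjusted over the list alone, camera adjusted p = 0.00013, adjusted p = 0.179 with an estimated correlation). They include Ciita, the activator of antigen presentation genes (log2 change -1.18), and Ms4a1, which encodes CD20 (-0.81).

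The PI3K genes moved both ways. Of 18 activating members 6 rose and 1 fell (6 and 1 adjusted over the list alone). Cd19 was the 1 that fell. The p110-delta gene Pik3cd rose (339 ± 26.2 against 233 ± 3.72 TPM), as did the regulatory subunit genes Pik3r5 (45.5 ± 5.81 against 24.1 ± 1.09 TPM) and Pik3r2 (log2 change 0.66). The list as a whole did not pass (camera adjusted p = 0.619). Of 18 members that restrain the pathway, 10 rose and 3 fell (11 and 3 adjusted over the list alone), without a call (camera adjusted p = 0.285). The PI3K inhibitor gene Pik3ip1 rose (114 ± 3.39 against 43.6 ± 4.56 TPM), and so did the inhibitory adaptor genes Dok3 and Dok2 (log2 change 0.73 and 1.28). The inhibitory Fc receptor gene Fcgr2b fell (41.0 ± 0.491 against 130.5 ± 2.81 TPM). FOXO target genes, which rise when PI3K is low, split as well (10 rose and 4 fell (10 and 5 adjusted over the list alone) of 18, camera adjusted p = 0.353). Ccr7 and Cited2 were higher (log2 change 0.88 and 1.28) and the lymphocyte egress receptor gene S1pr1 lower (-1.48).

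Genes of growth and division were lower in deficient lymph node cells. Of 27 cell cycle genes, 24 fell (25 adjusted over the list alone), with a median log2 change of -0.96 (camera adjusted p = 4.94e-15, adjusted p = 0.179 with an estimated correlation). The DNA topoisomerase gene Top2a fell by 1.35 on the log2 scale, and Mki67, a marker of dividing cells, went from 21.6 ± 1.93 to 7.15 ± 1.06 TPM. Of 22 ribosome biogenesis genes, 18 fell (19 adjusted over the list alone, camera adjusted p = 1.17e-08, adjusted p = 0.179 with an estimated correlation). The nucleophosmin gene Npm1 stood at 94.7 ± 9.57 against 181 ± 6.12 TPM. Of 16 glycolysis genes 1 rose and 8 fell (2 and 8 adjusted over the list alone). This list passed downward (camera adjusted p = 0.00208, adjusted p = 0.179 with an estimated correlation), with Ldha at a log2 change of -0.55. Of 17 cholesterol synthesis genes 7 fell, a count that was 7 adjusted over the list alone (camera adjusted p = 0.000226, adjusted p = 0.423 with an estimated correlation). Sqle was among them (-1.07). Germinal centre markers moved the same way, 1 higher and 7 lower of 11 (1 and 8 adjusted over the list alone). Their median log2 change was -1.28 (camera adjusted p = 6.07e-05, adjusted p = 0.179 with an estimated correlation). The deaminase gene Aicda fell from 26.5 ± 3.52 to 6.29 ± 0.758 TPM, and Rgs13, Gcsam and S1pr2 fell as well (log2 change -2.33, -1.77 and -1.41).

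Immediate-early, NF-kB target and interferon response genes were higher as lists in deficient lymph node cells. Of 27 immediate-early genes 18 rose and 4 fell (18 and 4 adjusted over the list alone). Their median log2 change was 0.67 (camera adjusted p = 0.000431, adjusted p = 0.521 with an estimated correlation). Among them were Ccl4 (31.2 ± 6.10 against 4.43 ± 0.489 TPM), Dusp5 (log2 change 1.49) and Nr4a3 (1.08). Of 21 NF-kB target genes 14 rose and 1 fell (15 and 1 adjusted over the list alone). This list passed upward (camera adjusted p = 0.00939, adjusted p = 0.643 with an estimated correlation). Traf1 and Relb were higher (log2 change 1.28 and 0.90) and Cd83 lower (-0.93). Of 19 interferon response genes 15 rose (16 adjusted over the list alone, camera adjusted p = 2.68e-05, adjusted p = 0.473 with an estimated correlation). Irf7 stood at 265 ± 5.20 against 139 ± 10.9 TPM and Isg15 at 138 ± 10.7 against 70.1 ± 5.67 TPM. Plasma cell genes did not move as a list (5 rose and 3 fell (6 and 3 adjusted over the list alone) of 16, camera adjusted p = 0.879). Sdc1 and the plasma cell factor gene Prdm1 rose, while Fkbp11 and Igj fell. Activation and class switch genes split (7 rose and 6 fell (7 and 8 adjusted over the list alone) of 20). Their mean was 0.13, their median -0.15 and the test pointed down without a call (camera adjusted p = 0.839). Stress genes split too (5 rose and 3 fell (5 and 3 adjusted over the list alone) of 13, camera adjusted p = 0.839), with Gadd45b higher (log2 change 1.16). Of 14 marginal zone and B1 cell markers 9 rose and 2 fell (9 and 3 adjusted over the list alone), without a list call (camera adjusted p = 0.296), with Cd9 higher (log2 change 1.15).

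Myeloid and dendritic cell markers were higher in the same deficient lymph node libraries. Of 20 myeloid markers 17 rose (19 adjusted over the list alone). Their median log2 change was 1.06 (camera adjusted p = 6.66e-07, adjusted p = 0.179 with an estimated correlation). Among them were Ly6c2 (158 ± 15.8 against 36.7 ± 2.95 TPM) and Tyrobp (331 ± 8.11 against 195 ± 5.04 TPM). All 12 dendritic cell markers rose (12 adjusted over the list alone), by a median of 0.98 (camera adjusted p = 2.59e-05, adjusted p = 0.179 with an estimated correlation). The most abundant, Cst3, stood at 3185 ± 352 against 1114 ± 11.6 TPM. Of 16 T cell markers 6 rose and 2 fell (6 and 2 adjusted over the list alone), without a list call (camera adjusted p = 0.285). Tcf7 and Cd4 were higher (log2 change 1.64 and 1.00) and Cd2, which mouse B cells also express, lower (-1.95). Of 8 NK cell markers 2 rose (camera adjusted p = 0.404), Klrb1c and Klrk1, and both calls ended without lymph node control replicate 1 (adjusted p = 0.0824 and 0.0625). Of 3 stromal and endothelial markers 1 rose (camera adjusted p = 0.337). Of 2 erythroid and platelet markers limma called 0, with 0 at an unadjusted p under 0.05 (median 0.05, test downward, camera adjusted p = 0.839). Each list call named for lymph node cells was lost when the correlation between genes was estimated. Without lymph node control replicate 1 the number of genes past the threshold was 3292.

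**Figure D2:**
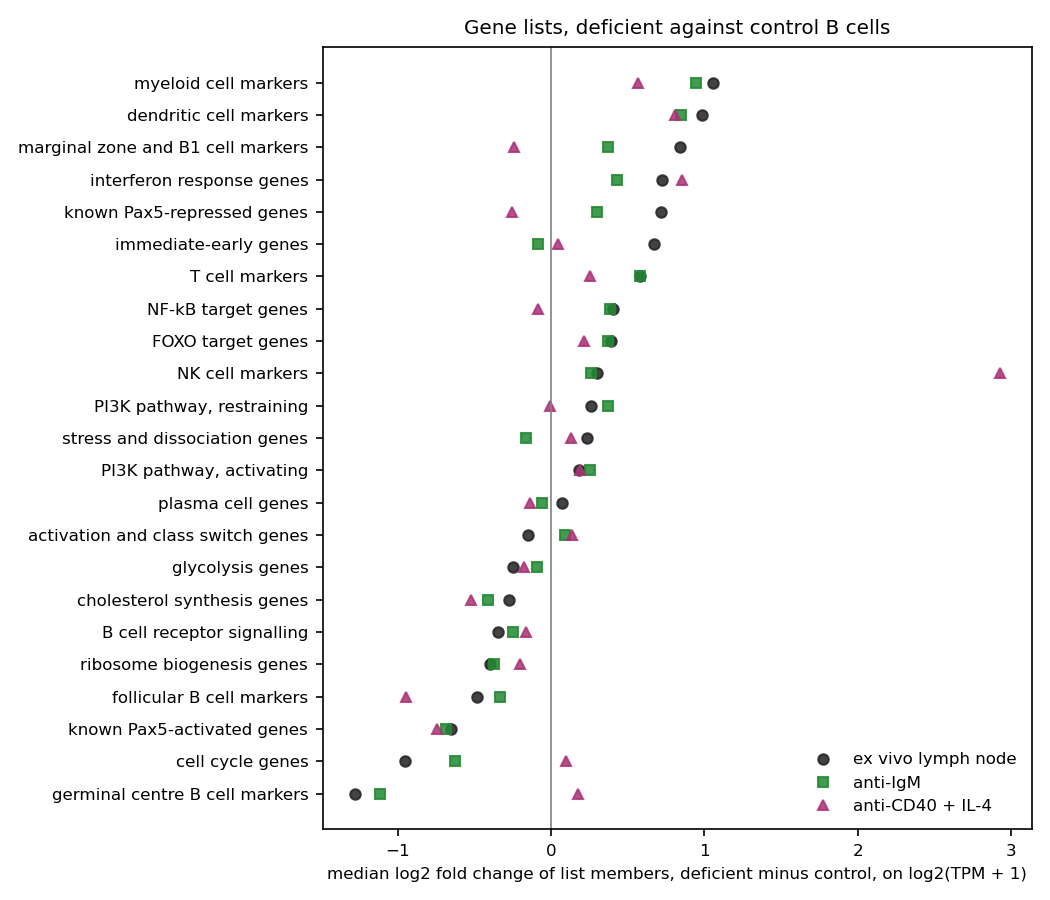
Median log2 fold change, deficient minus control, of the tested members of each list with at least 5 tested members, in lymph node, anti-IgM and anti-CD40 libraries. Cell cycle genes lie at -0.96 in lymph node and -0.63 in anti-IgM libraries and at 0.10 in anti-CD40 libraries, and genes known to need Pax5 lie below 0 in each condition.

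The anti-IgM comparison asks how the genotypes differ 1 hour after the B cell receptor is engaged. Deficient cells again had more Sdc1 (130.5 ± 3.07 against 11.2 ± 0.994 TPM), Il2ra (79.7 ± 0.608 against 12.3 ± 0.0281 TPM) and Car2 (235 ± 23.2 against 27.9 ± 0.370 TPM). They had less Cr2 (11.7 ± 1.13 against 98.5 ± 6.83 TPM) and less Cd19 (log2 change -1.19). They held less of the growth regulator gene Myc (838 ± 25.7 against 2454 ± 121 TPM) and of the receptor-induced genes Egr1 (228 ± 0.946 against 889 ± 7.41 TPM) and Egr2 (125 ± 5.37 against 595 ± 5.71 TPM). The plasma cell and activation factor gene Irf4 was lower too (648 ± 18.3 against 1638 ± 12.6 TPM). The phosphatase gene Dusp5 was higher (764 ± 52.9 against 106 ± 8.53 TPM), and so was Klf2, a FOXO target that keeps lymphocytes resting (809.9 ± 26.7 against 225 ± 19.7 TPM). Of 12084 genes 6304 passed the limma test, 4090 higher and 2214 lower, and 1063 changed at least 2-fold. The largest rises included Col27a1 (log2 change 3.47), Sema6d (3.33), Osgin1 (2.97), the Notch ligand gene Jag2 (2.95), the transferrin gene Trf (2.85), Arl4c (2.80) and Cd93 (2.79). The largest falls included Rasd1 (-3.11), B3gnt7 (-2.91), Cacna1i (-2.91), Stac2 (-2.74), Cd55 (-2.66), Crb3 (-2.59), Rgs13 (-2.44), Hs3st1 (-2.31) and Shank1 (-2.31). The median log2 change of all genes was 0.10 and moved to -0.06 with rescaling, which turned the calls to 3024 higher and 3857 lower.

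Several gene groups kept their lymph node direction after anti-IgM. B cell receptor signalling genes fell as a list (7 rose and 13 fell (7 and 13 adjusted over the list alone) of 25, camera adjusted p = 0.00324, adjusted p = 0.406 with an estimated correlation). Genes known to need Pax5 fell as well (4 rose and 17 fell (4 and 17 adjusted over the list alone) of 24, camera adjusted p = 9.51e-07, adjusted p = 0.39 with an estimated correlation), among them the transcription factor gene Spib (log2 change -1.20). Genes that Pax5 is known to hold down did not pass as a list (8 rose and 2 fell (8 and 2 adjusted over the list alone) of 17, camera adjusted p = 0.0538). Of 27 cell cycle genes 22 fell (24 adjusted over the list alone, camera adjusted p = 1.97e-10, adjusted p = 0.39 with an estimated correlation). Of 22 ribosome biogenesis genes 2 rose and 12 fell (2 and 12 adjusted over the list alone) (camera adjusted p = 2.43e-06, adjusted p = 0.39 with an estimated correlation). The genes of nucleophosmin, Npm1, and nucleolin, Ncl, were lower (log2 change -1.26 and -0.82). Cholesterol synthesis genes fell (2 rose and 11 fell (2 and 11 adjusted over the list alone) of 17, camera adjusted p = 0.000164, adjusted p = 0.406 with an estimated correlation). Follicular markers fell (2 rose and 8 fell (2 and 8 adjusted over the list alone) of 13, camera adjusted p = 0.00251, adjusted p = 0.39 with an estimated correlation). Germinal centre markers fell (1 rose and 6 fell (1 and 6 adjusted over the list alone) of 11, camera adjusted p = 0.00324, adjusted p = 0.406 with an estimated correlation). Interferon response genes rose, 11 of 19 (13 adjusted over the list alone, camera adjusted p = 0.0113, adjusted p = 0.761 with an estimated correlation). Myeloid markers rose in these libraries too (16 rose and 1 fell (17 and 1 adjusted over the list alone) of 20, camera adjusted p = 0.000513, adjusted p = 0.39 with an estimated correlation). Dendritic cell markers rose with them (10 of 12 up, 10 adjusted over the list alone, camera adjusted p = 0.00251, adjusted p = 0.39 with an estimated correlation). Immediate-early genes split (10 rose and 13 fell (10 and 13 adjusted over the list alone) of 27, camera adjusted p = 0.0627). Among PI3K genes the adaptor gene Pik3ap1 fell (915 ± 2.13 against 1639 ± 55.3 TPM) and Pik3cd rose (159.6 ± 6.32 against 88.1 ± 3.65 TPM). Pik3ip1 and the Akt phosphatase gene Phlpp1, which restrain the pathway, rose (log2 change 1.24 and 1.75). Neither PI3K list nor the FOXO list passed (camera adjusted p = 0.878 for the activating, 0.149 for the restraining and 0.0576 for the FOXO genes).

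The next comparison asks how each genotype responded to anti-IgM, with lymph node cells taken ex vivo as the reference. No group was held for 1 hour without the antibody, so each response holds the incubation as well as anti-IgM. The cell label of the treated libraries names no organ, so a difference of organ would be part of each response too. Control cells switched on the nuclear receptor genes Nr4a3, from 7.23 ± 0.533 to 2733 ± 57.3 TPM, and Nr4a1, from 47.7 ± 2.74 to 5359 ± 90.8 TPM. The chemokine gene Ccl4 went from 4.43 ± 0.489 to 966 ± 2.38 TPM and Irf4 from 79.5 ± 0.880 to 1638 ± 12.6 TPM. Deficient cells raised these genes as well. Nr4a3 went from 16.4 ± 1.56 to 1251 ± 43.2 TPM, Nr4a1 from 51.8 ± 8.74 to 3299 ± 16.4 TPM and Irf4 from 64.2 ± 6.46 to 648 ± 18.3 TPM. In control cells 7891 genes passed the limma test, 2931 higher and 4960 lower. In deficient cells 7694 passed, 3002 higher and 4692 lower, and at least 2-fold changes numbered 2337 and 2048. Of the 2931 genes that rose in control cells 2452 also rose in deficient cells and 23 fell, and of the 4960 that fell 4049 also fell and 37 rose. Other strong rises in control cells were Plk2 (log2 change 6.65), Fosl2 (6.42), Atf3 (6.33), Crem (6.32), the angiogenic factor gene Vegfa (6.20) and Chac1 (5.92). The strongest falls were B3gnt8 (-4.42), Calhm2 (-3.65), the cytokine genes Il16 (-3.37) and Ltb (-3.08), and the costimulatory ligand gene Icosl (-3.34). In deficient cells the growth factor gene Tgfb3 (5.69) and the decoy receptor gene Il1r2 (5.63) were also among the largest rises, and Tmem173, which encodes the DNA sensor adaptor STING, was among the falls (-2.92).

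As a list, immediate-early genes rose in control cells (24 rose and 2 fell (24 and 2 adjusted over the list alone) of 27, median log2 change 3.16, camera adjusted p = 1.71e-13, adjusted p = 0.882 with an estimated correlation). They rose in deficient cells too (23 rose and 2 fell (24 and 2 adjusted over the list alone), median 2.34, camera adjusted p = 3.25e-12, adjusted p = 0.819 with an estimated correlation). Ribosome biogenesis genes rose in control cells (18 of 22, 18 adjusted over the list alone, camera adjusted p = 8.55e-10, adjusted p = 0.882 with an estimated correlation). In deficient cells 20 rose and 1 fell (20 and 1 adjusted over the list alone) (camera adjusted p = 2.73e-10, adjusted p = 0.819 with an estimated correlation). The nucleolar gene Gnl3 was up in both (log2 change 2.91 and 2.39). NF-kB target genes rose in control cells (15 rose and 5 fell (15 and 5 adjusted over the list alone) of 21, camera adjusted p = 0.000383, adjusted p = 0.882 with an estimated correlation), with Rel going from 73.7 ± 1.42 to 844 ± 32.5 TPM. Deficient cells gave a like result (14 rose and 4 fell (14 and 4 adjusted over the list alone), camera adjusted p = 0.00155, adjusted p = 0.894 with an estimated correlation). Stress genes rose, 9 of 13 in control cells (9 adjusted over the list alone, camera adjusted p = 0.000341, adjusted p = 0.882 with an estimated correlation). In deficient cells 7 rose (7 adjusted over the list alone, camera adjusted p = 0.0104, adjusted p = 0.894 with an estimated correlation). Atf4 and Ddit3 were among them. Interferon response genes fell, 14 of 19 in control cells (14 adjusted over the list alone, camera adjusted p = 0.00258, adjusted p = 0.882 with an estimated correlation). In deficient cells 18 fell (18 adjusted over the list alone, camera adjusted p = 5.78e-05, adjusted p = 0.819 with an estimated correlation). Stat1 was lower in both (log2 change -1.22 and -1.05). Pten rose by 0.66 in control cells (adjusted p = 0.000989) and by 0.59 in deficient cells (adjusted p = 0.00207). These responses did not differ by the test (difference -0.07, adjusted p = 0.859). Pax5 fell in control (-0.32, adjusted p = 0.0104) and deficient cells (-0.40, adjusted p = 0.0038). The control call ended without lymph node control replicate 2 (adjusted p = 0.0842), without anti-IgM control replicate 1 (0.0574) and with rescaling (0.19). Among myeloid and dendritic markers 14 of 20 and 9 of 12 were lower after anti-IgM in deficient cells, without a list call (camera adjusted p = 0.141 for each). They leaned down in control cells too, with median log2 changes of -0.60 and -0.53, against -0.64 and -0.72 in deficient cells. The median log2 change of all genes was -0.19 in control and -0.16 in deficient cells and moved to -0.02 and -0.01 with rescaling, which brought the falls to 3911 and 3801 genes.

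The difference between these responses was tested gene by gene. Atf3 and Nr4a3 rose less and Tgfb3 rose more in deficient cells (difference 2.60 for Tgfb3). Atf3 went from 2.51 ± 0.196 to 282 ± 11.4 TPM in control and from 6.71 ± 0.679 to 129.9 ± 1.31 TPM in deficient cells. Nr4a3 rose by 8.38 and 6.17 on the log2 scale (difference -2.21, adjusted p = 3.54e-05). Klf2 fell in control cells, from 556 ± 25.8 to 225 ± 19.7 TPM, and rose in deficient cells, from 341 ± 21.6 to 809.9 ± 26.7 TPM. The difference was 2.55 (adjusted p = 2.97e-05). S1pr1, like Klf2 a FOXO target, went from 169 ± 9.27 to 137 ± 0.303 TPM in control and from 60.1 ± 3.45 to 171 ± 4.06 TPM in deficient cells. The insulin receptor substrate gene Irs2, also in the FOXO list, and the PI3K adaptor gene Pik3ap1 rose less in deficient cells (differences -1.94 and -0.72). Of 18 FOXO targets 7 had a more positive and 6 a more negative response at an unadjusted limma p under 0.05. The FOXO list did not pass. Foxo1 and the Akt phosphatase gene Phlpp1 rose in deficient cells by more than in control cells (differences 0.97 and 1.30), where neither response passed. In all 843 of 12084 genes had a response that differed by the limma test, 484 more positive and 359 more negative in deficient cells. The majority turned with scaling, from 57.4% more positive to 46.6% with median-ratio rescaling and with DESeq2, and 35.8% with edgeR on recovered reads. Immediate-early genes stood out as a list. Of 27 members 1 had a more positive and 15 a more negative response in deficient cells (2 and 16 adjusted over the list alone). Their median difference was -0.86 (camera adjusted p = 3.1e-12, adjusted p = 0.833 with an estimated correlation). Stress genes had a lower response (3 of 13, 4 adjusted over the list alone, camera adjusted p = 0.00149, adjusted p = 0.833 with an estimated correlation). Among 3408 genes that rose on average over both genotypes, 267 rose less and 178 rose more in deficient cells, and among 5652 that fell on average, 260 fell less and 67 fell more. The count of 843 became 425 in 1 fit of all 12 libraries and 1374 with edgeR on recovered reads. It ranged from 339 without anti-IgM control replicate 2 to 1292 without lymph node deficient replicate 1. It was 417 and 385 without lymph node control replicate 1 and 2. It was 466 without anti-IgM control replicate 1, and 439 and 414 without anti-IgM deficient replicate 1 and 2.

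**Figure D3:**
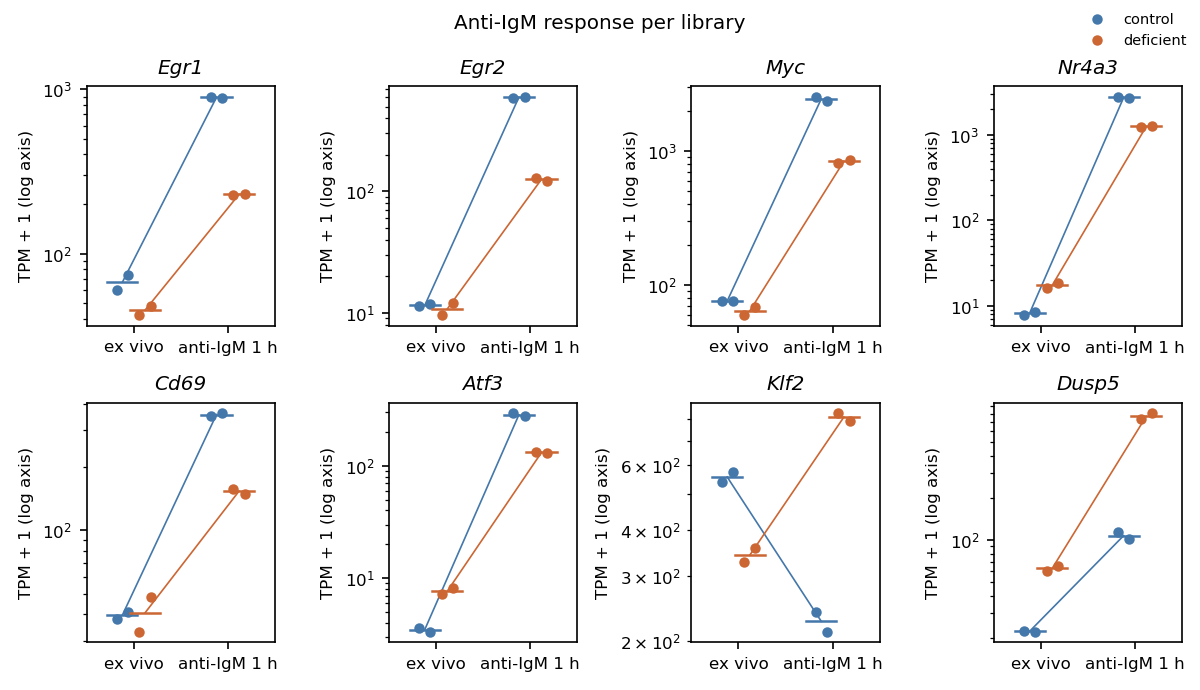
Level of 8 genes in each library of ex vivo lymph node cells and of cells 1 hour after anti-IgM, as TPM + 1 on a log axis, with points for libraries and lines joining the group means. Egr2, Myc and Nr4a3 end lower in deficient than in control cells, and Klf2 falls in control cells and rises in deficient cells.

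The culture with anti-CD40 and interleukin 4 asks what Pax5 does in dividing B cells. Deficient cells there had less Cd79a, a signalling chain of the B cell receptor (255 ± 1.79 against 1446 ± 14.9 TPM), and less Cd19 (318 ± 15.4 against 803 ± 26.8 TPM). The inhibitory receptor genes Cd72 (7.98 ± 0.441 against 74.1 ± 20.5 TPM) and Fcgr2b (1.46 ± 0.237 against 23.5 ± 2.71 TPM) were lower as well. Deficient cultures had more of the T cell factor Tcf7 (117 ± 6.01 against 17.5 ± 1.33 TPM) and of the granzyme genes Gzmb (20.8 ± 0.412 against 0.237 ± 0.214 TPM) and Gzma (13.4 ± 0.164 against 0.208 ± 0.293 TPM). The granzyme genes are in the NK cell marker list, and bulk libraries do not show which cells of the cultures held them. Aicda, the deaminase for class switching, was higher too (196 ± 40.8 against 43.8 ± 13.3 TPM), while the IgG1 heavy chain (log2 change -1.11) and the CD23 gene Fcer2a (-0.95) fell. The activation and class switch list they belong to did not pass (3 rose and 4 fell (3 and 4 adjusted over the list alone) of 20, mean 0.07, median 0.14, test downward, camera adjusted p = 0.615). Of 10962 genes 577 passed the limma test, 361 higher and 216 lower, and 373 changed at least 2-fold. Rises also included Tnni1 (log2 change 3.65), Gnaz (3.45), Sertad4 (3.18), Capsl (2.95), Cacnb2 (2.86), the interleukin 7 receptor gene Il7r (2.80) and Pik3r5 (1.65). Falls included the chemokine receptor gene Ackr3 (-3.89), Scn4a (-3.21), Chst10 (-3.11), Crhbp (-3.08), Gstt2 (-3.03), the IgM Fc receptor gene Faim3 (-2.62), Lipg (-2.61) and the follicle homing receptor gene Cxcr5 (-1.69). Ccl5, Plac8 and Cacnb3 rose on unequal libraries (60.4 ± 42.2, 418 ± 234 and 14.0 ± 12.3 TPM in deficient cells). Plac8 lost its call with robust hyperparameters (adjusted p = 0.0804) and Cacnb3 without either control replicate (0.207 and 0.15). Ccl5, and the properdin gene Cfp and the IgD heavy chain, which fell, lost theirs without control replicate 1 (0.054 each).

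As a list, follicular markers fell in the cultures (1 rose and 8 fell (1 and 11 adjusted over the list alone) of 13, camera adjusted p = 1.04e-12, adjusted p = 0.2 with an estimated correlation). Genes known to need Pax5 fell (3 rose and 11 fell (3 and 14 adjusted over the list alone) of 24, camera adjusted p = 1.64e-09, adjusted p = 0.2 with an estimated correlation), Nedd9 among them (log2 change -1.50). Cholesterol synthesis genes fell (6 of 17, 13 adjusted over the list alone, camera adjusted p = 2.65e-13, adjusted p = 0.2 with an estimated correlation). B cell receptor signalling genes fell (0 rose and 6 fell (1 and 7 adjusted over the list alone) of 25, camera adjusted p = 1.33e-05, adjusted p = 0.367 with an estimated correlation). NF-kB target genes leaned down (1 rose and 3 fell (2 and 8 adjusted over the list alone) of 21, camera adjusted p = 0.0021, adjusted p = 0.525 with an estimated correlation). Ribosome biogenesis and glycolysis genes passed downward with 0 genes called by limma (5 of 22 and 4 of 16 lower at an unadjusted p under 0.05, 0 and 2 adjusted over the list alone). The first had camera adjusted p = 5.79e-05, adjusted p = 0.597 with an estimated correlation. The second had camera adjusted p = 0.0021, adjusted p = 0.56 with an estimated correlation, and its call ended without anti-CD40 deficient replicate 2 (0.0988). Genes that Pax5 is known to hold down went lower as a list here (0 rose and 1 fell (1 and 3 adjusted over the list alone) of 12, camera adjusted p = 0.0108, adjusted p = 0.597 with an estimated correlation). The call ended without control replicate 1 (adjusted p = 0.0589), control replicate 2 (0.326) and deficient replicate 2 (0.0988). Interferon response genes rose (3 of 14, 6 adjusted over the list alone, camera adjusted p = 8.58e-05, adjusted p = 0.716 with an estimated correlation). Of 4 NK cell markers 3 rose (3 adjusted over the list alone, camera adjusted p = 8.58e-05, adjusted p = 0.303 with an estimated correlation). They were Gzma, Gzmb and Nkg7. The last was listed at 0 in both control libraries and lost its call without control replicate 1 (adjusted p = 0.054). Cell cycle genes gave no call (0 of 27 by limma, 4 higher at an unadjusted p under 0.05, camera adjusted p = 0.615). Neither PI3K list passed (camera adjusted p = 0.615 for the activating and 0.0784 for the restraining genes). Myeloid and dendritic markers gave medians of 0.57 and 0.81 over 9 and 5 tested members. Limma called 0 of them, with 3 of each higher and 1 myeloid marker lower at an unadjusted p under 0.05 (camera adjusted p = 0.408 and 0.0784). Without 1 control library, the spread was estimated from the 2 deficient libraries alone. These varied more than the control pair (SD of the log2 ratio 0.425 against 0.363). The counts that follow therefore do not show that the control libraries decided this comparison. Without control replicate 1 it had 74 genes and without replicate 2 128, and 32 and 28 of the 62 named genes with a call lost it. With edgeR and DESeq2 on recovered reads 980 and 965 genes passed.

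The conditions shared part of the genotype effect. Of 10596 genes tested in each condition, 203 were higher in deficient cells in all 3 (31.6 would be so by chance if the calls were independent) and 86 were lower in all 3 (6.45 by chance). Their sum of 289 became 153 without a filter, 747 in 1 fit of all 12 libraries, and 490 and 458 with edgeR and DESeq2 on recovered reads. The share of higher genes went from 70.2% to 52.0% with rescaling. Car2 was higher by 3.16, 3.03 and 2.35 on the log2 scale in lymph node, anti-IgM and anti-CD40 cells, and Tcf7 by 1.64, 1.79 and 2.68. Cd19 fell in each (-1.21, -1.19 and -1.33), and so did Fcgr2b (-1.65, -0.95 and -3.31). Across genes, which are not independent replicates, log2 changes in lymph node cells had a Pearson r of 0.779 (Spearman rho 0.771) with those after anti-IgM and of 0.287 (rho 0.169) with those after anti-CD40. The 2 lowest shared counts came without anti-CD40 control replicates 1 and 2, at 43 and 75 genes in both directions together.

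The small RNA comparison asks which microRNAs differ after loss of Pax5, in CD23-sorted B cells. The labels do not say whether the protocol (mime-seq) enriched the microRNAs of a certain cell type. In spleen follicular cells the lymphocyte microRNA miR-150-5p fell from 64219.8 ± 1412 to 17033 ± 1153 TMM-scaled CPM (counts-per-million). There miR-33-5p, which targets cholesterol export, fell from 5141 ± 1250.5 to 791 ± 166. The miR-29b-1-3p row fell from 29447 ± 1092 to 10142 ± 186 and the miR-181a-1-5p row rose from 2921 ± 34.7 to 7859 ± 1619. These scaled values are not shares of a library, and the sizes of the changes depend on the scaling. The log2 change of the miR-29b-1-3p row in spleen was -1.54 with TMM and -0.69 with library totals alone. The myeloid microRNA miR-223-3p rose from 923 ± 61.1 to 3481 ± 7.62. The p53 target miR-34a-5p rose from 182 ± 39.7 to 691 ± 123, and miR-455-3p from 75.0 ± 17.8 to 453 ± 35.6. In lymph node cells the same 7 moved alike: miR-150-5p, miR-33-5p and miR-29b-1-3p fell (log2 change -1.24, -2.06 and -0.83), and miR-181a-1-5p, miR-223-3p, miR-34a-5p and miR-455-3p rose by 1.01, 2.34, 2.10 and 2.99. Of 668 rows tested with edgeR 149 passed in spleen, 85 higher and 64 lower, and 103 in lymph node, 52 higher and 51 lower. Other large changes in spleen were miR-141-3p (log2 change -2.03), miR-219a-2-5p (-2.42), miR-142b-3p (-2.41) and miR-142a-5p (-1.78). In lymph node they were miR-203-3p (1.47), miR-200b-3p (1.08), miR-141-3p (-1.59), miR-190b-5p (-1.45) and miR-200c-3p (-1.24). The rise of miR-99a-5p in spleen (log2 change 2.41) rests on unequal control libraries (19.1 ± 15.3 CPM) and was 3.63 and 1.62 without control replicate 1 and 2. The rise of miR-1a in spleen came from 1 deficient library (0.919 and 98.0 CPM), and miR-144-3p, at 1045 ± 987 in control spleen, lost its call without control replicate 1 (adjusted p = 0.0843).

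By family, miR-29 fell relative to other microRNAs in spleen (7 of 8, 7 adjusted over the list alone, camera adjusted p = 3.66e-07, adjusted p = 0.0987 with an estimated correlation). It fell in lymph node too (3 of 8, 5 adjusted over the list alone, camera adjusted p = 0.000104, adjusted p = 0.206 with an estimated correlation). Its medians were -0.96 and -0.37, but -0.10 and 0.01 with scaling to library totals alone. The miR-181 family rose under both scalings, by a median of 1.31 in spleen and 0.91 in lymph node. In spleen 11 of 12 rose (11 adjusted over the list alone, camera adjusted p = 1.53e-08, adjusted p = 0.0987 with an estimated correlation). In lymph node 9 rose (10 adjusted over the list alone, camera adjusted p = 1.2e-08, adjusted p = 0.121 with an estimated correlation). Of 51 rows of microRNAs known to target Pten, 11 rose and 13 fell (13 and 15 adjusted over the list alone) in spleen (camera adjusted p = 0.362). In lymph node 6 rose and 7 fell (11 and 10 adjusted over the list alone) (mean 0.02, median -0.06, test downward, camera adjusted p = 0.372). The rows hold both arms and each genomic copy of a microRNA, so minor arms and repeated copies are counted too. With library totals alone 45 of the 51 rows lay above 0 in spleen (median 0.74) and 43 in lymph node (median 0.32), so the even split rests on the scaling. This shift is not particular to microRNAs that target Pten. With library totals 21 of 21 let-7 rows and 42 of 47 lymphocyte rows lay above 0 in spleen too, against 3 of 8 miR-29 rows. The most abundant of them, miR-21a-5p, was 50975 ± 3930.3 in deficient and 35039 ± 11344 in control spleen and did not pass (adjusted p = 0.0951). The let-7 family leaned down in spleen (1 rose and 2 fell (1 and 2 adjusted over the list alone) of 21, camera adjusted p = 0.00211, adjusted p = 0.58 with an estimated correlation). The call ended without spleen control replicate 1 (adjusted p = 0.0921), and the direction turned with library totals (median 0.62). It did not pass in lymph node (camera adjusted p = 0.109). The miR-17~92 family did not pass (2 rose and 6 fell (2 and 6 adjusted over the list alone) of 30 in spleen, camera adjusted p = 0.362 there and 0.33 in lymph node). With library totals alone 29 of its 30 rows lay above 0 in spleen (median 0.75), and miR-19a-3p, miR-20a-5p and miR-17-5p passed upward there. Lymphocyte microRNAs did not pass as a list either (13 rose and 6 fell (14 and 6 adjusted over the list alone) of 47, camera adjusted p = 0.394 and 0.97). Of microRNAs of other cells, myeloid ones rose in spleen (6 of 7, 6 adjusted over the list alone, camera adjusted p = 0.000144, adjusted p = 0.224 with an estimated correlation). Endothelial and stromal ones rose there as well (4 of 13, 11 adjusted over the list alone, camera adjusted p = 0.000144, adjusted p = 0.58 with an estimated correlation). Neither passed in lymph node (camera adjusted p = 0.103 and 0.0551), and erythroid ones passed in neither organ (camera adjusted p = 0.631 and 0.97). With library totals alone 452 rows passed in spleen, 432 of them higher, and 209 in lymph node, 191 of them higher. The spleen count fell to 81 with the 4 spleen libraries alone, and the lymph node count rose to 210 with the 4 lymph node libraries. Leaving out lymph node control replicate 1 or 2 brought the lymph node count of 103 to 34 and 40, and deficient replicate 1 or 2 to 33 and 34.

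**Figure D4:**
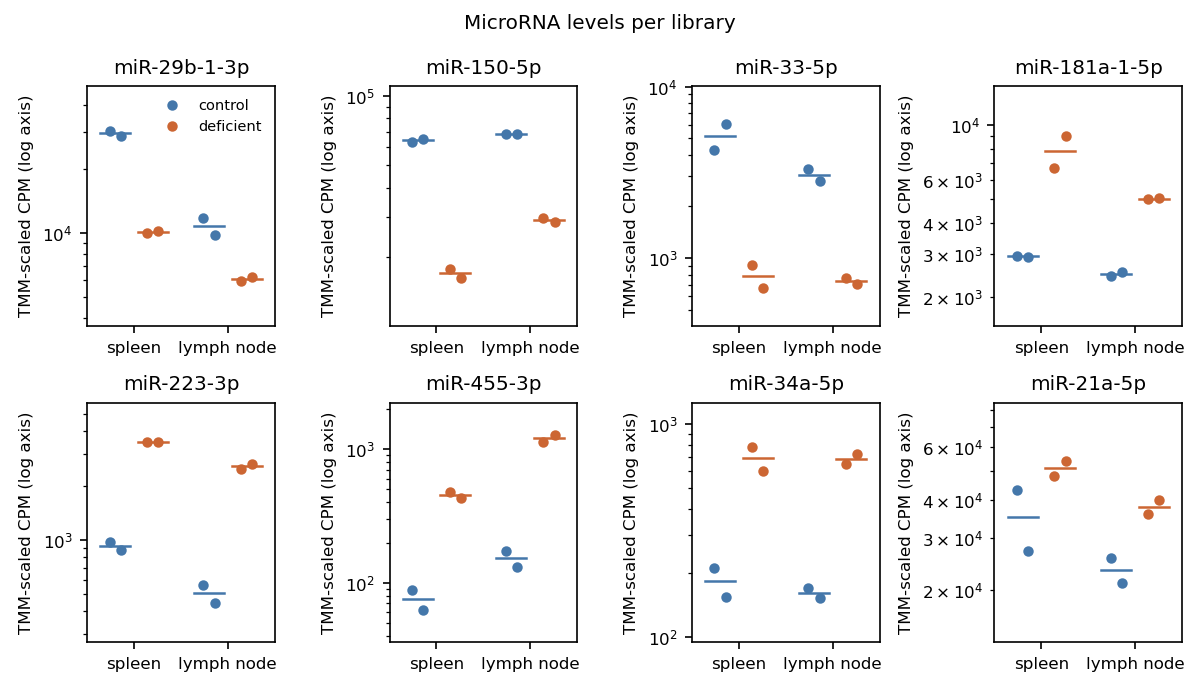
Level of 8 microRNA rows in each small RNA library, in TMM-scaled CPM, by organ and genotype, with a point for each of the 2 libraries and a bar at their mean. miR-150-5p and miR-33-5p are lower, and miR-223-3p and miR-455-3p higher, in the deficient libraries of both organs.

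The genotype effect differed between the organs for 7 of 668 rows by edgeR (83 at an unadjusted p under 0.05). The fall of miR-150-5p and miR-142a-5p was deeper in spleen (differences 0.68 and 1.22, adjusted p = 0.0428 each). The level of miR-29c-3p went from 2989.8 ± 161 to 1120.1 ± 138 in spleen and stood at 3096 ± 335 and 2355 ± 223 in lymph node (difference 1.02, adjusted p = 0.0436). With library totals alone the difference of miR-29c-3p was 0.56 (adjusted p = 0.0738), and 2 of the 7 calls ended. As lists, miR-29 (1 of 8 by edgeR, 6 adjusted over the list alone, camera adjusted p = 4.74e-06, adjusted p = 0.245 with an estimated correlation) had the less negative effect in lymph node. The miR-181 family had the smaller rise there (camera adjusted p = 0.0013, adjusted p = 0.3 with an estimated correlation, no single row by edgeR, 4 at an unadjusted p under 0.05). The myeloid list leaned lower in lymph node (1 of 7, 2 adjusted over the list alone, camera adjusted p = 0.0135, adjusted p = 0.528 with an estimated correlation). The endothelial list did too (camera adjusted p = 0.00327, adjusted p = 0.8 with an estimated correlation, edgeR 0 of 13, 0 at an unadjusted p under 0.05). The myeloid call ended without spleen deficient replicate 1 (adjusted p = 0.0521) and without lymph node control replicate 1 (0.0989), and the endothelial call without spleen control replicate 2 (0.731). The 7 rows are few and fragile: 14 and 35 rows passed without spleen control replicate 1 and 2, and 0 without spleen deficient replicate 2 or any 1 lymph node library. Spleen files list 1394 rows and lymph node files 1512, so organ and processing set cannot be told apart in this difference.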

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

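Of the tests in this part, the one of the TPM scale for immediate-early genes was chosen before its result was seen, and the others were chosen after the patterns they address had been seen.

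The response to anti-IgM differed between the genotypes, by a test of the difference itself, for these 10 genes. Tgfb3 rose in both and more in deficient cells (difference 2.60, adjusted p = 3.02e-05). Klf2 and the ubiquitin ligase gene Neurl3 fell in control and rose in deficient cells (differences 2.55 and 2.39). Rasd1 went from 1.05 ± 0.116 to 68.0 ± 10.0 TPM in control and from 1.05 ± 0.257 to 6.97 ± 0.440 TPM in deficient cells (difference -3.11), and Prrg4 from 2.72 ± 0.234 to 40.7 ± 2.06 and from 3.93 ± 0.593 to 8.80 ± 0.0329 TPM (difference -2.49). Ccl3, Ccl4 and Atf3 rose less in deficient cells (differences -3.07, -2.98 and -2.25). Lrrc10b and Etnk2 stood near 0 before stimulation (2.52 and 2.25 on the scale used). Their calls rest on the pseudocount: on recovered reads the difference of Lrrc10b was -0.91 with edgeR and -0.15 with DESeq2, and Etnk2 had an adjusted p of 0.758 and 0.726.

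The genotype effect differed between lymph node and spleen, again by its own test, for 7 microRNA rows. It was less negative in lymph node for miR-142b-3p (2.11), miR-142a-5p (1.22), miR-29c-3p (1.02) and miR-150-5p (0.68), and lower in lymph node for miR-338-3p (-1.49), miR-22-3p (-1.39) and miR-674-5p (-1.28). In lymph node miR-142b-3p and miR-338-3p stood at few CPM (2.45 against 3.02 and 2.41 against 2.98, deficient against control). MiR-22-3p, listed as targeting Pten, was called higher in deficient spleen (5195 ± 369 against 3710 ± 651 CPM) and lower in deficient lymph node (417 ± 20.8 against 783 ± 12.9 CPM). By means miR-674-5p went opposite ways too (66.5 against 45.1 and 40.1 against 66.1 CPM). The adjusted p values lay between 0.0351 and 0.0436, and none of the 7 passed when any 1 lymph node library or spleen deficient replicate 2 was left out.

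Between lymph node and anti-CD40 cells 56 genes were called in opposite directions, 32 higher and 24 lower in lymph node. In 1 fit of all 12 libraries, where culture and preparation go together, the effects differed for 2476 of 12486 genes. Aicda fell in lymph node and rose in the cultures (difference 4.07), as did the G protein gene Gnaz (4.53). Cfp and Dok2 rose in lymph node and fell in the cultures (-4.07 and -2.98). These 4 were singled out after their values were seen.

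The first pattern weighed is the rise of myeloid and dendritic cell markers in deficient lymph node libraries. A lower share of B cells, which raises each other cell type alike, cannot be told apart from a change in these cells. The median log2 ratio was 0.786 for T cell, 1.32 for myeloid and 1.11 for dendritic cell markers. The T cell and myeloid medians lay apart by less than the SD over T cell members (0.824). They lay apart by more than the SD over myeloid (0.506) and dendritic members (0.403). Of 17 T cell markers 15 were higher, but their summed TPM went from 585 in control to 324 in deficient libraries. The sum fell through the few members that were not higher. Cd2, which mouse B cells also express, was among these, so the sum does not measure T cells alone. NK cell markers (0.329) lie near the floor and decide nothing. Expression of the markers within deficient B cells stays open and cannot be told apart from the other accounts, since their median in anti-CD40 cultures was 0.67 over 14 of 32 members. More myeloid and dendritic cells in the deficient preparations cannot be told apart either: 32 of 32 markers were higher by mean TPM, but they are the pattern itself, so the count does not favour this account. CD43 depletion should clear most such cells. The most abundant markers were Cst3 (3185 ± 352 against 1114 ± 11.6 TPM), Bst2 (374 against 183 TPM) and Tyrobp (331 ± 8.11 against 195 ± 5.04 TPM). Control lymph node libraries had 29 of the 32 at 1 TPM or more, and Csf1r, Fcer1g and Flt3 are also in the list of Pax5-repressed genes.

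The second pattern is the lower level of cell cycle genes in deficient lymph node cells. The TPM scale as the whole cause is argued against, since the median log2 change was -0.96 before and -1.08 after median-ratio rescaling. A candidate explanation is fewer germinal centre B cells in the deficient lymph nodes, whose markers fell at least as far (median -1.28) and share 0 genes with the cell cycle list. Depletion of CD43-positive cells was not shown to remove these cells, and of their 2 most abundant markers Basp1 rose (251 ± 35.5 against 157 ± 8.83 TPM) and Bcl6 did not pass (119 against 144 TPM), while Stap1 fell (33.0 against 80.6 TPM). Slower division of the other B cells was not tested.

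The third pattern is the smaller rise of immediate-early genes after anti-IgM in deficient cells. The TPM scale as the whole cause is argued against, since the median difference was -0.86 before and -0.90 after rescaling. A higher starting level as the whole cause is too, since 12 of the 15 members with a smaller rise also ended lower in deficient cells. Dilution by cells that do not respond would lower the rise of strongly induced members alike if those cells began at the same level. The differences were uneven, with an SD of 0.853 against a median standard error of 0.144 (14 members, -0.26 for Fosl2 to -3.07 for Ccl3). Their spread does not decide on dilution, since each difference holds the ex vivo level too. Ccl3 began higher in deficient cells (log2 change 3.21). Over all genes 178 of 445 rising genes with a difference rose more in deficient cells, but 260 of 327 falling genes with one fell less, so dilution stays open. A higher starting level still has a part, since 10 of the 15 began higher ex vivo and 7 both began higher and ended lower, Ccl3 ended no lower, and Junb and Dusp1 ended higher (log2 change 0.49 and 0.46). A weaker early response to the B cell receptor after loss of Pax5 stays open, as a hypothesis found and tested on the same data. The effect of incubation, of the organ the treated cells came from and of the time between dissection and stimulation was not tested. Cells of new animals held for 1 hour with and without anti-IgM would test the hypothesis.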

How the results depend on the processing

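Fits on recovered reads, library totals, 1 count column alone and rescaled lists were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers that groups share. Where a library was left out, the lone sample was assumed to vary like the other groups. Where no cause is named, the cause was not tested.

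Of 9234 values for named genes and microRNAs, over all settings but the 2-fold threshold, 8658 kept direction and side of the threshold, 498 lost their call, 34 gained one and 44 changed direction. With all libraries 6211 of 6435 kept both, and with 1 library left out 2447 of 2799. The 2-fold threshold kept 383 of 532. By comparison, named calls that held in every setting were 88 of 94 in lymph node, 93 of 99 after anti-IgM, 27 of 62 after anti-CD40, 30 of 58 for the difference of responses, 25 of 53 in spleen, 23 of 35 in lymph node microRNAs and 0 of 7 between organs. List calls held in 46 of 46 cases with rescaling and 242 of 250 with a library left out, and 57 of 57 were lost with an estimated correlation. With that setting no list passed in any comparison, including immediate-early genes in the control response (median log2 change 3.16). Its losses therefore do not tell the lists apart. Rescaling without immunoglobulin segments gave no value for the named immunoglobulin genes, and a fit of 1 organ gives none for the difference between organs.

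The 2-fold threshold left 1003 genes in lymph node, 1063 after anti-IgM, 373 after anti-CD40, 2337 and 2048 for the responses of control and deficient cells and 245 for their difference, by its construction. The anti-CD40 count was 319 without a filter, 2231 in 1 fit of 12 libraries, and 980 and 965 with edgeR and DESeq2 on recovered reads. The difference of responses gave 425 in the 12-library fit and 1374 with edgeR. Genes shared by 3 conditions numbered 153 without a filter, 747 in the 12-library fit, and 490 and 458 with edgeR and DESeq2. For microRNAs library totals gave 452 in spleen, 209 in lymph node and 77 between organs, and fits of 1 organ gave 81 and 210. Between organs RLE gave 13, DESeq2 17 and no filter 22.

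With 1 library left out the counts ranged from 3292 to 5363 in lymph node, 4548 to 5007 after anti-IgM, 74 to 579 after anti-CD40, 6645 to 6860 and 6542 to 7590 for the responses, 339 to 1292 for their difference, 43 to 284 for shared genes, 112 to 174 in spleen, 33 to 40 in lymph node microRNAs and 0 to 35 between organs. Anti-CD40 control replicate 1 gave the lowest anti-CD40 and shared counts (74 and 43), replicate 2 the next (128 and 75), and lymph node control replicate 1 gave 3292.

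The split into higher and lower moved with scaling. The share of higher genes was 64.7% in lymph node against 44.1% after median-ratio rescaling, 48.6% with edgeR and 44.4% with DESeq2, and 64.9% after anti-IgM against 44.0%, 41.5% and 44.2%. It was 62.6% after anti-CD40 against 51.3% with rescaling and 49.6% with DESeq2, 37.1% and 39.0% for the responses against 50.7% and 51.1%, 57.4% for their difference against 46.6% and 35.8% with edgeR, and 70.2% for shared genes against 52.0%. Library totals moved the median microRNA by 0.89 in spleen and 0.42 in lymph node and gave 95.6% and 91.4% higher.

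Directions turned as follows, with the range over left-out libraries after each. Pax5 in lymph node turned to -0.0864 with rescaling, -0.0710 with edgeR and -0.0892 with DESeq2 (-0.0493 to 0.162 with 1 library left out). Ranges alone crossed 0 for Pten in lymph node (-0.205 to 0.126), Pax5 after anti-IgM (-0.0438 to 0.00397), and Pax5 (-0.182 to 0.0294) and Pten (-0.237 to 0.0939) in the difference of responses. Pten after anti-CD40 turned to -0.0698 with rescaling, -0.0694 with edgeR and -0.0888 with DESeq2 (-0.296 to 0.371). Lrrc10b turned to -0.91 with edgeR and -0.15 with DESeq2. With library totals these spleen rows turned: miR-29c-5p 0.0360, miR-29a-5p 0.0562, miR-19a-3p 0.40, miR-20a-5p 0.41, miR-17-5p 0.42, miR-19b-1-3p and miR-19b-2-3p 0.52, let-7f-2-3p 0.12, let-7i-3p 0.44 and miR-26b-5p 0.59. In lymph node they were miR-19a-3p 0.00251, let-7f-2-5p 0.0728, miR-29a-3p 0.0592 and miR-26b-5p 0.0988. Both miR-26a-5p rows crossed 0 in spleen (-0.147 to 0.278 each). Between organs miR-21a-5p turned to -0.29 with library totals (-0.217 to 0.609), and miR-26b-5p to 0.0554 without a filter and 0.0178 with 1 count column (-0.122 to 0.170).

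On simulated data 55.2% of 2-fold changes were recovered in the anti-CD40 comparison and 46.3% in the difference between organs, against 100% in lymph node. The simulated dispersion was 0.0218 for the 4 anti-CD40 libraries and 0.0237 for small RNA. It was 0.00452 for the 8 other RNA libraries. The parts of the loss due to dispersion, to the number of libraries and to the form of the comparison were not separated.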

Other observations

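The gene groups in this part were chosen after their values were seen, and so was the test of miR-29 targets. Antigen presentation genes of the class II pathway were lower in deficient cells of each condition: 10 of 10 passed in lymph node cells, 10 of 10 after anti-IgM and 6 of 10 after anti-CD40 (median log2 change -0.56, -0.59 and -0.65). The peptide editor gene H2-DMb2 went from 1506 ± 31.2 to 637 ± 6.92 TPM in lymph node cells, and Ciita, which drives the pathway, from 340.2 ± 21.4 to 149.5 ± 12.1 TPM. Among transcription factors of other lineages 12 of 13 were higher in lymph node cells, 11 of 13 after anti-IgM and 2 of 11 after anti-CD40. Tcf7 and Lef1, which guide T cell development, were the 2 that passed in each condition (log2 change 1.64, 1.79 and 2.68 for Tcf7, and 1.74, 1.66 and 1.16 for Lef1). Lef1 is also in the list of genes known to need Pax5. Spi1 stood at 325 ± 14.8 TPM in control lymph node cells, so members of this group are also expressed in control B cell preparations. Id2, Klf4, Cebpa and the dendritic cell factor gene Batf3 rose in lymph node cells (1.47, 1.70, 1.48 and 1.91), where myeloid and dendritic markers were also higher.

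Transcription factors of B cells leaned lower, with 8 of 12 lower and 1 higher in lymph node cells, 7 and 2 after anti-IgM, and 3 and 1 after anti-CD40. The coactivator gene Pou2af1 fell in each condition (log2 change -1.01, -0.45 and -0.66), and Lmo2 did too (-0.55, -0.67 and -1.35). Ebf1, which acts with Pax5 in early B cells, did not pass in lymph node cells (log2 change -0.01, limma adjusted p = 0.967). Of 9 Toll-like receptor genes and their relatives 3 were higher and 1 lower in lymph node cells, with Tlr2 higher (1.05) and the LPS response regulator gene Cd180 lower (-0.99). Spn, which encodes CD43, the antigen used for depletion, was higher in deficient cells of each condition (log2 change 0.34, 0.80 and 1.43), at 34.2 ± 1.86 against 26.8 ± 0.489 TPM in lymph node cells.

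MicroRNAs of the miR-29 family repress collagen and other matrix transcripts, so their fall could raise the messages they target. Of 34 listed targets 20 were tested in lymph node cells, 6 higher and 3 lower by limma (7 and 3 adjusted over the list alone), and camera gave p = 0.269, with p = 0.722 for an estimated correlation. The test does not decide whether lower miR-29 raised its targets. The fall itself depends on scaling. With library totals alone miR-29b-1-3p still fell in spleen (log2 change -0.69, edgeR adjusted p = 0.000424) and lymph node (-0.44, 0.0116), and miR-29a-3p in spleen stood at -0.05 (adjusted p = 0.741).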
